A study of Mus musculus with 15 samples.

How the data were processed

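The series held 15 single-cell libraries, 12 of sorted macrophages and 3 of sorted pancreas fibroblasts. Each came as a matrix of raw UMI counts per gene and barcode that the authors deposited without normalization. Per the submitters' processing notes, libraries were made with 10x Chromium 3' chemistry and counted with Cell Ranger 4.0.0 against mm10. The file headers gave version 4.0.0 for 13 libraries with 32285 features and version 3.1.0 for the 2 steady-state macrophage libraries with 33456 features. Genes were therefore tested or compared across these libraries only for the 26565 identifiers found in both references. Droplets had been called as cells before deposit.

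Pancreas macrophages had been sorted per the labels as live CD45, CD11b and F4/80 positive cells, after exclusion of cells positive for CD3, CD19, B220, SiglecF, Ly6G or Ly6C, and split by YFP. Pancreatitis had been induced with repeated cerulein at 100 ug per kg. Steady-state and cerulein-treated pancreas had been digested for a shorter time than tumors. The YFP mice were C57BL/6, and the tdTomato and fibroblast mice were FVB/NJ.

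Barcodes were kept with at least 500 detected genes and at most 15% mitochondrial counts. Kept cells ranged from 2404 in YFP-positive PDAC to 17983 in steady-state fibroblasts. The 5 sets of libraries (YFP pancreas, liver, lung, fibroblasts and tdTomato) were clustered apart from each other. Counts were scaled to 10000 per cell, and 2000 variable genes, 30 principal components and 20 neighbours fed Leiden clustering at resolution 1 with 5 iterations, after Jaccard pruning of the neighbour graph. Clusters were named from 26 fixed marker lists when at least 3 markers of a type stood out, and then checked against their 10 leading genes, detected in at least 10% of cells. A PDAC cluster with Mmp12, Cxcl3 and Arg1 among its leading genes had Arg1, a marker fixed for another class, and no macrophage marker among the 10, and was held out. Clusters of low UMI content for their own libraries, clusters with no clear type and the held-out cluster left 6.89% and 7.56% of steady-state, 9.56% and 30.1% of pancreatitis and 35.4% and 31.3% of PDAC cells, YFP-positive and YFP-negative, without a name. In PDAC the held-out cluster was 462 of the 850 YFP-positive and 1228 of the 2431 YFP-negative cells without a name. Doublets were scored against simulated doublets with 30 neighbours and called at 0.8% per 1000 barcodes.

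Counts were summed per library over macrophages, with Kupffer and alveolar cells added where the liver and lung entered, or over fibroblasts. The sums held 69229048 and 70962781 UMIs at steady state, 42794988 and 75738905 in pancreatitis, and 42640612 and 107865959 in PDAC, for YFP-positive and YFP-negative macrophages. At these depths Col1a1 at 7.74 CPM in YFP-negative macrophages of pancreatitis had a Poisson interval of 7.12 to 8.39 CPM. Intervals cover counting error only.

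The lineage contrast was the only one with 3 libraries on each side. It was fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) with disease state as a block, over 3 pancreas pairs and over 5 pairs, with Benjamini-Hochberg adjusted p under 0.05. DESeq2 1.42.0 ran beside it. Each SE given is the size of the edgeR log2 fold change divided by the square root of its F statistic. Fold changes were fitted within states or tissues, so they need not match the ratio of the mean CPM printed beside them. The state contrast was set before the files were read as 1 library against 1 within each lineage, and was not tested. State, processing day and reference could not be separated in it. For 25 gene lists camera in limma 3.58.1 used a preset correlation of 0.01, with an estimated correlation and fry beside it. The lists were resident macrophage, monocyte-derived macrophage, MHC class II, collagen and matrix proteins, matrix proteases and inhibitors, growth factor ligands, inflammatory cytokines and chemokines, alternative activation, lipid-associated macrophage, complement, phagocytosis receptors, interferon response, cell cycle, glycolysis and hypoxia, dissociation stress, acinar secretory, fibrillar collagen and collagen processing, myofibroblast, inflammatory fibroblast, universal fibroblast, antigen-presenting fibroblast, TGF-beta response, Kupffer cell, alveolar macrophage, and receptors of fibroblasts. Some genes sit in several lists, such as Col1a1, Vsig4 and H2-Aa.

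Every other comparison had 1 library per group. Values there are CPM, counts scaled to a common library total, with exact Poisson 95% intervals, log2 ratios with 1 CPM added, and list medians over genes with at least 20 counts in both libraries together. Each median was placed among 10000 random lists of the same size, drawn within windows of 100 genes of like expression. A percentile describes these libraries and is no test between groups. The disease states share their steady-state libraries, so pancreatitis and PDAC over steady state are not independent of each other. Shares of cells carry Clopper-Pearson intervals.

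The lists, tests and alternatives were fixed before the data were examined, except where stated. Named genes followed a fixed rule. For the lineage contrast it took genes past the test, with the same sign in every pair and a mean of at least 20 CPM, and it named none. For single libraries it took the 10 largest ratios in each direction among genes with at least 50 CPM in a library and 50 counts. Mitochondrial, ribosomal, hemoglobin, immunoglobulin, acinar, sex-linked and predicted genes were left out of the ranking. Members of the fixed lists could be named whatever their value. Cell Ranger drops reads shared by overlapping genes, so counts of Spp1, S100a4, C2, Cd74, Col3a1, Ctla2a and Uba52, which overlap another gene on their strand, are uncertain.

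Alternatives were DESeq2, its size factors in edgeR, no filter on low counts, all cells that passed the quality filter, no cycling clusters, no called doublets, a stricter filter (1000 genes, 10% mitochondrial), no state block, leaving out each pair, adding the tdTomato pair, leaving out acinar, stress and other marker genes, TMM scaling and weighting each cell the same. Chosen after seeing the data were the PDAC cluster with Arg1 added to the class, the doublet and stricter filters for the list test, list medians without genes low in the steady-state libraries, and Kupffer or alveolar cells alone.

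The pipeline was tested on simulated data. Counts were drawn with the libraries' own depth and with edgeR's spread of each gene, an estimate drawn toward that of other genes. With 100 genes changed 2-fold or 4-fold, edgeR called 98 and 100 over 3 pairs with 20 false calls among 13224 genes. Over 5 pairs it called 76 and 96 with 8 false calls among 13120. DESeq2 called 99 at each size over 3 pairs with 35 false calls, and 92 and 96 over 5 pairs with 52 false calls. Set against all calls made, false calls took a larger share than the adjusted p threshold allows for edgeR over 3 pairs. The same held for DESeq2 over 3 and over 5 pairs, but not for edgeR over 5 pairs. Genes called by DESeq2 in the real data may therefore include more false calls than its threshold states. Of 100 null lists 5% fell outside the limits that hold 95% of random lists, and 10 of 10 raised lists lay above them. The remaining tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, python-igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9 and R 4.3.3. Sex-linked genes, differential splicing and the YFP and tdTomato transcripts were not analysed here.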

Results

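The series measured gene expression in single cells sorted from mouse pancreas, liver and lung. Of the 15 libraries, 12 held macrophages and 3 held pancreas fibroblasts, and each group was 1 library. In Flt3-Cre;LSL-YFP mice, cells that passed through an Flt3-expressing blood progenitor carry YFP. Lack of YFP did not exclude such a history, since dendritic cells and monocytes were also found in YFP-negative sorts. YFP-positive and YFP-negative macrophages were sorted from the pancreas at steady state, in pancreatitis brought on by cerulein and in pancreatic ductal adenocarcinoma (PDAC) grown from 100000 implanted KPC-1 cells. The same sort was made in liver tumors 14 days after 500000 KPC-2 cells and in lung tumors after 1000000 KPL86 cells. A further pair held tdTomato-positive and tdTomato-negative macrophages of pancreatitis, where a tamoxifen pulse marks cells that expressed Csf1r before the injury. The 3 fibroblast libraries came from untreated pancreas, from pancreatitis with control IgG and PBS liposomes, and from pancreatitis with anti-CSF1 and clodronate liposomes, which deplete macrophages. Nothing in the labels says that libraries came from separate animals, so no p-value below measures the spread between animals. Those of edgeR, DESeq2 and fry rest on the spread between these libraries only. Camera compares the genes of a list with other genes, and at the preset correlation takes genes as nearly independent. Its p-values at that setting, and that of Fisher's exact test, which counts genes, do not measure how far a result repeats over libraries.

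Depth was counted in UMIs, the distinct RNA molecules read. Total UMI counts of the YFP-positive and YFP-negative libraries were 79218789 and 76756908 at steady state, 67538164 and 152388864 in pancreatitis, 65138170 and 171030945 in PDAC, 121991190 and 160894082 in liver tumor, and 191173601 and 175510017 in lung tumor. The tdTomato-positive and tdTomato-negative libraries held 82297337 and 60747557 UMIs. The fibroblast libraries held 129663106 UMIs at steady state, 149287881 with IgG and 162352069 after depletion. After the quality filter, the median cell held from 6569 UMIs in steady-state fibroblasts to 23393 in the YFP-positive PDAC library. The filter removed most barcodes of 2 libraries, since 8363 of 22160 YFP-negative barcodes of pancreatitis (37.7%) and 7764 of 18050 of PDAC (43.0%) were kept.

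Cells named as macrophages from marker genes such as Adgre1, Csf1r and C1qa made up 83.3% (Clopper-Pearson 95% interval 82.4 to 84.3, counting error only) of YFP-positive and 89.1% (88.4 to 89.8) of YFP-negative cells at steady state. In pancreatitis these shares were 63.5% (62.1 to 64.9) and 59.9% (58.8 to 60.9), and in PDAC 54.8% (52.8 to 56.8) and 59.4% (58.3 to 60.5). Type 2 conventional dendritic cells, which use Flt3, made up 2.38% of YFP-positive and 0.199% of YFP-negative cells at steady state, 9.76% and 2.45% in pancreatitis, and 6.24% and 4.08% in PDAC. Monocytes made up 14.6% of YFP-positive and 4.28% of YFP-negative cells in pancreatitis, against 1.06% and 0.112% at steady state. In the liver, Kupffer cells, which express Clec4f and Timd4, were 17.7% (16.9 to 18.5) of YFP-positive and 80.9% (80.3 to 81.5) of YFP-negative cells. In the lung, alveolar macrophages, which express Siglecf and Ear1, were 44.7% (43.9 to 45.5) of YFP-positive and 86.8% (86.3 to 87.3) of YFP-negative cells. Fibroblasts were 93.2%, 92.6% and 91.4% of the steady-state, IgG and depleted fibroblast libraries. These shares describe sorted suspensions and not tissues.

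The first comparison asked what separates macrophages without the YFP mark from those with it in all 3 states of the pancreas. Genes of resident macrophages stood higher in YFP-negative macrophages. Lyve1, the hyaluronan receptor of perivascular macrophages, had a mean of 411 CPM in the 3 YFP-negative and 251 CPM in the 3 YFP-positive libraries (log2 fold change 1.24, SE 0.251, n = 3 pairs), with log2 ratios of 0.49, 1.44 and 1.81 at steady state, in pancreatitis and in PDAC. The scavenger receptor gene Cd163 stood at 402 against 217 CPM (0.99, SE 0.159), and Timd4, which encodes a receptor for dying cells, at 69.6 against 41.5 CPM (1.77, SE 0.450). Ccr2, the receptor that draws monocytes from blood, was at 322 against 506 CPM (−0.78, SE 0.458), and its ratio went from −2.21 at steady state and −0.41 in pancreatitis to 0.30 in PDAC. The antigen-presentation gene H2-Eb1 was at 2498 against 3296 CPM (−0.52, SE 0.182). Signs of RNA quality moved in the pancreatitis pair, where summed mitochondrial transcripts stood at 72413 against 52665 CPM (log2 ratio 0.46). Ribosomal protein transcripts stood there at 88312 against 123532 CPM (−0.48). At steady state and in PDAC mitochondrial ratios were −0.15 and 0.08 and ribosomal ones 0.02 and 0.09. Among signs of other cells, hemoglobin stood at 4.65, −0.39 and 4.51 and immunoglobulin at −2.24, −0.43 and 0.99 in the 3 pairs. At steady state most YFP-negative macrophages fell in a cluster led by Cd209f and Lyve1 (48.1%) and another led by Lilra5 and H2-Eb1 (37.9%), while YFP-positive macrophages were spread over the second of these (32.2%), a cluster led by Lyz1 and Retnla (27.3%) and the first (26.7%). In pancreatitis 54.0% of YFP-negative and 75.1% of YFP-positive macrophages fell in a cluster led by Arhgap30, Ccr2 and Gdf3 (Arhgap30 stood near 0 in both steady-state libraries, which had been counted with another software version), and a cluster led by Vsig4 and C4b held 26.8% of the YFP-negative. In PDAC a cluster led by Nrg1, Jaml and Il1b held 70.3% of the YFP-negative and 80.6% of the YFP-positive macrophages.

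No gene passed the edgeR test at an adjusted p under 0.05 among 13483 genes, in either direction. At an unadjusted p under 0.05 edgeR gave 743 genes higher and 425 lower in YFP-negative macrophages, 8.66% of those tested, and DESeq2 at an adjusted p under 0.05 gave 150 higher and 42 lower. In simulated data over 3 pairs, DESeq2 made more false calls than this threshold allows. The same direction in all 3 pairs was seen for 2598 genes higher (19.3%) and 1633 lower (12.1%), where even odds for each sign give 12.5% each way. These ratios used library totals, and the median gene stood at 0.07 in the pancreatitis pair, so 12.5% is no exact chance level. The genes named next were chosen after their values were seen. Pla2g2d, a secreted phospholipase of resident macrophages, had the lowest edgeR p (54.5 against 26.3 CPM, log2 fold change 1.10, SE 0.0995, adjusted p = 0.232). Colec12, a scavenger collectin, stood at 83.4 against 27.8 CPM (1.67, SE 0.194, edgeR adjusted p = 0.271), and its DESeq2 adjusted p was 5.96e-12. The chemokine Ccl5 stood at 15.6 against 28.7 CPM (−0.98, SE 0.142). DESeq2 also called Cd209f, Lyve1 and the complement gene C4b higher, and Plaur, Fabp5 and Gpnmb lower. The edgeR count hung on single pairs: it was 43 genes higher without the steady-state pair and 3 without the pancreatitis pair.

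Gene lists gave a different count. Of 25 fixed lists, 14 passed camera (limma, preset correlation) at an adjusted p under 0.05, and 0 passed with an estimated correlation, the lowest of those adjusted p being 0.140. All 23 genes of the resident macrophage list stood higher in YFP-negative macrophages, 21 of them in all 3 pairs (median log2 fold change 0.67, camera adjusted p = 6.05e-33, adjusted p = 0.140 with an estimated correlation). In this list 18 genes passed edgeR when adjusted over the list alone, among them Lyve1 (adjusted p = 0.00893), Gas6 (528 against 301 CPM, adjusted p = 0.00678), Vsig4 (103 against 27 CPM, adjusted p = 0.0226) and Folr2. All 22 genes of the monocyte-derived list stood lower (median −0.72, camera adjusted p = 1.07e-13, 0.395 with an estimated correlation), with 9 lower in all 3 pairs and 0 past the edgeR test adjusted over the list alone. All 10 MHC class II genes stood lower in all 3 pairs (−0.39, adjusted p = 5.75e-11, 0.343 with an estimated correlation), and H2-Oa alone passed adjusted over the list alone (−1.57, SE 0.332, adjusted p = 0.0331). Without the steady-state pair 22 lists passed, all 14 among them, and without the pancreatitis or PDAC pair 16 and 15 passed, with 12 and 13 of the 14 among them.

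Matrix genes formed another group. Of 31 measured genes of collagens and matrix proteins, 25 stood higher and 6 lower in YFP-negative macrophages (median 0.95, camera adjusted p = 9.08e-15, 0.343 with an estimated correlation), 16 of them past edgeR adjusted over the list alone. Their levels were low: Col1a1, a chain of fibrillar collagen, stood at 4.04 against 1.45 CPM (log2 fold change 1.24, SE 0.239), Col3a1 at 7.42 against 2.74 CPM (1.35, SE 0.221) and Dcn at 10.5 against 5.53 CPM (0.95, SE 0.193). The abundant members Fn1 and Spp1 stood lower, Fn1 at 1316 against 1503 CPM (−0.97, SE 0.636) with ratios of −3.03, −0.20 and 0.16 in the 3 pairs, and Spp1, whose exons overlap Gm42793, at 742 against 834 CPM (−0.78, SE 0.304). The fibrillar collagen and processing list had 20 of 23 genes higher (median 0.79, adjusted p = 6.13e-15, 0.343 with an estimated correlation, 9 past edgeR adjusted over the list alone). In the same libraries Col1a1, Col1a2 and Col3a1 together were also higher in other immune cells of the YFP-negative side, at 19.7 against 3.37 CPM in pancreatitis and 9.89 against 2.43 CPM in PDAC, beside 32.6 against 9.84 and 10.6 against 4.08 CPM in macrophages. Enzymes that acinar cells make moved the same way: all 18 measured genes stood higher in YFP-negative macrophages (median 0.72, camera adjusted p = 3.83e-32, 0.140 with an estimated correlation), among them Clps at 361 against 225 CPM (1.04, SE 0.187) and Prss2 at 179 against 109 CPM. In this list 17 genes passed edgeR adjusted over the list alone, and other immune cells held acinar RNA too. By fry, the acinar list moved on balance upward (adjusted p = 0.0176) and the resident list did not pass (adjusted p = 0.138).

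Among the remaining lists past camera at the preset correlation, lipid-associated genes stood lower (median −0.32, 14 of 18 lower, adjusted p = 1.28e-05, 0.343 with an estimated correlation), with 6 past edgeR adjusted over the list alone, such as Gpnmb (21.3 against 36.1 CPM, −0.91, SE 0.244) and Fabp5 (206 against 295 CPM, −0.96, SE 0.234). Glycolysis and hypoxia genes also stood lower (−0.25, adjusted p = 3.54e-05, 0.397 with an estimated correlation), Gapdh being at 851 against 1075 CPM, as did inflammatory cytokines and chemokines (−0.15, 0.00163, 0.343 with an estimated correlation). Higher were Kupffer cell genes (0.49, 10 of 13 higher, adjusted p = 0.000251), growth factor ligands (0.15, 14 of 21, 0.00512), complement (0.02, 7 of 11, 0.00512) and myofibroblast genes (0.36, 10 of 13, 0.0323), each at 0.343 with an estimated correlation. Receptors of fibroblasts were higher too (0.15, 11 of 15, adjusted p = 0.00924, 0.449 with an estimated correlation). Growth factor ligands and receptors of fibroblasts did not pass without the pancreatitis pair (adjusted p = 0.101 and 0.181), nor did myofibroblast genes without the PDAC pair (0.470). In the complement list C4b stood at 440 against 210 CPM (1.06, SE 0.203) and C2, whose exons overlap Gm20547, at 19.1 against 6.47 CPM (1.70, SE 0.239). Igf1, a growth factor that acts on fibroblasts, stood at 238 against 144 CPM (0.67, SE 0.124). The lists that did not pass camera were matrix proteases and inhibitors (median −0.14, adjusted p = 0.129), phagocytosis receptors (0.10, 0.181), interferon response (0.04, 0.473, with a mean of −0.05), cell cycle (−0.07, 0.12), dissociation stress (−0.07, 0.183) and alternative activation (0.09, 0.690), whose mean was −0.16. Nor did the inflammatory fibroblast list (0.00, 0.921), the universal fibroblast list (0.31, 0.0876), the antigen-presenting fibroblast list (−0.14, 0.80, with a mean of 0.09), TGF-beta response (−0.08, 0.632, with a mean of 0.14) or alveolar macrophage genes (−0.38, 0.0945).

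**Figure D1:**
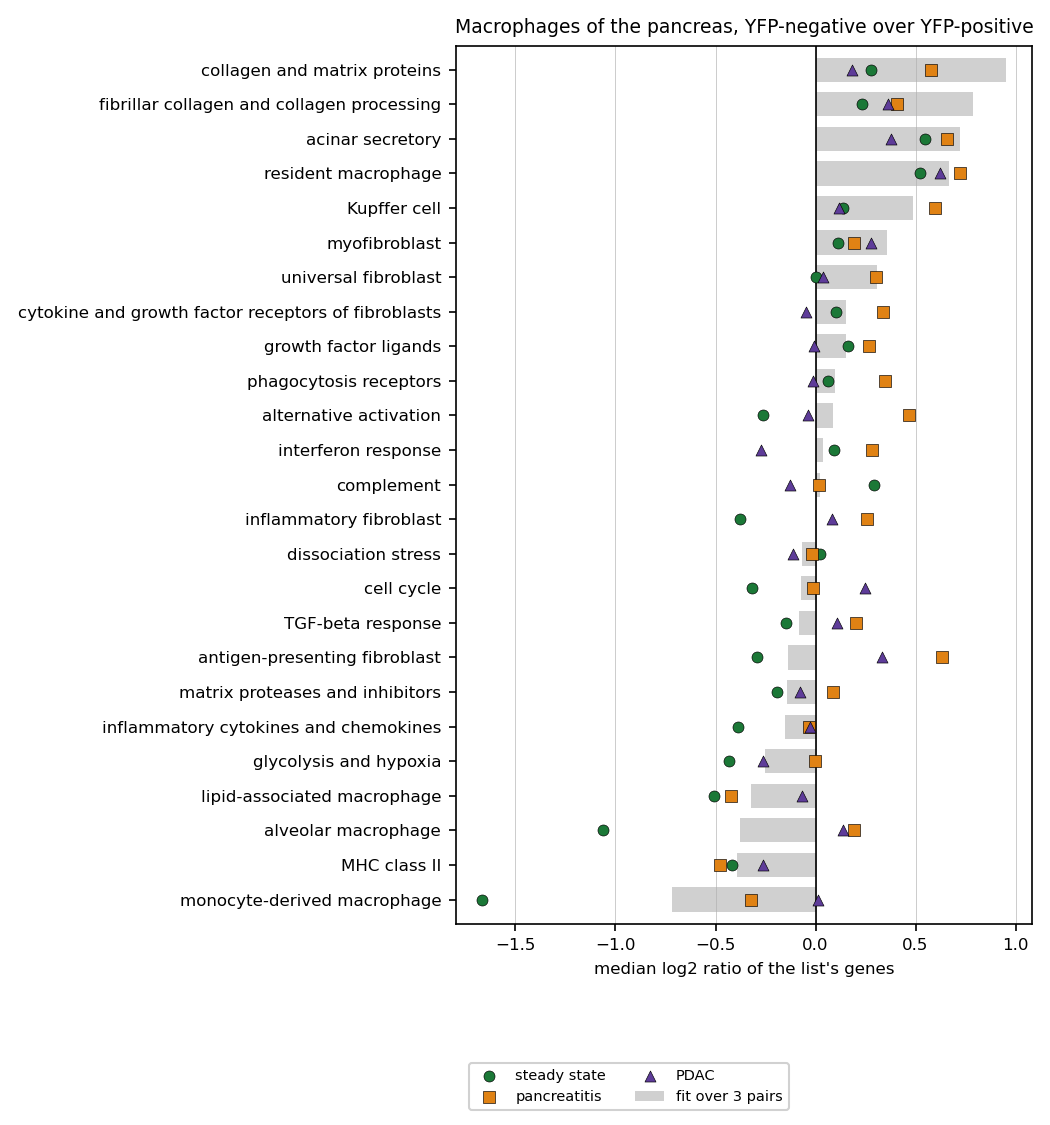
Median log2 ratio of YFP-negative over YFP-positive macrophages (x axis, no unit) for each of 25 gene lists (y axis), with grey bars for the fit over 3 pairs and markers for the steady-state, pancreatitis and PDAC pair. Resident macrophage genes lie at 0.52, 0.72 and 0.62 in the 3 pairs and MHC class II genes at −0.42, −0.48 and −0.26; markers add 1 CPM to each library, so lists of low genes lie nearer 0 than their bar.

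The second comparison added the liver and lung pairs, to ask which lineage differences held over 5 tissues or states. MHC class II genes were lower in YFP-negative macrophages in each of the 5 pairs for all 10 genes (median log2 fold change −0.99). Cell makeup differed between lineages in liver and lung, as given above, and in Kupffer cells alone and alveolar macrophages alone this list had medians of −0.30 and −0.59, against −1.20 and −1.53 in the whole classes, so the values over 5 pairs mix makeup with lineage. H2-Eb1 had a log2 fold change of −1.23 (SE 0.496, n = 5 pairs) and H2-Aa of −0.92, and Ccr2 was at −1.75. Colec12 was at 1.60 (SE 0.250) and C4b at 1.07 (SE 0.181). Dcn, a matrix proteoglycan, was at 7.31 against 3.73 CPM (1.05, SE 0.174, edgeR adjusted p = 0.0136 adjusted over the list alone). No gene among 13341 passed edgeR in either direction, with 1041 higher and 517 lower at an unadjusted p under 0.05 and 106 higher and 99 lower by DESeq2. In simulated data over 5 pairs, DESeq2 again made more false calls than its threshold allows. The same direction in all 5 pairs was seen for 1523 genes higher (11.4%) and 597 lower (4.47%), where even odds for each sign give 3.125% each way. These ratios used library totals, and the median gene stood at 0.18 in the liver pair and 0.08 in the lung pair. Part of the excess of higher genes may thus come from scaling, and 3.125% is no exact chance level.

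By camera at the preset correlation 13 lists passed over the 5 pairs, and 0 did with an estimated correlation, where the lowest adjusted p was 0.359. MHC class II (adjusted p = 8.41e-12) and monocyte-derived genes (median −1.34, 22 of 22 lower, 2.49e-12) were lower, each with an adjusted p = 0.359 with an estimated correlation. Inflammatory cytokines and chemokines had 20 of 21 genes lower (−0.66, adjusted p = 3.16e-08, 0.359 with an estimated correlation). Resident macrophage genes had 17 higher and 6 lower (median 0.47, adjusted p = 0.000743, 0.530 with an estimated correlation) and 0 past edgeR adjusted over the list alone. Collagens and matrix proteins had 20 of 29 higher (0.86, 2.42e-06, 0.529 with an estimated correlation), with 10 past edgeR adjusted over the list alone, and acinar enzymes 18 of 18 (0.82, 2.49e-12, 0.359 with an estimated correlation). These counts follow the sign of the fitted fold change. In all 5 pairs alike, 6 monocyte-derived and 4 inflammatory genes were lower. Higher in all 5 were 5 resident, 12 matrix and 3 acinar genes, and 1 matrix gene was lower in all 5. The acinar gene Try5, for example, stood at 0 CPM in both lung libraries and at 0.0204 against 0.0162 CPM in the liver. The other lists past camera were lower for lipid-associated (−0.67, adjusted p = 0.000753, 0.359 with an estimated correlation), glycolysis and hypoxia (−0.35, 2.45e-05, 0.525), dissociation stress (−0.23, 0.000645, 0.530), alternative activation (−0.72, 0.00390, 0.529) and matrix protease genes (−0.23, 0.0340, 0.529), and higher for fibrillar collagen (0.39, 2.42e-06, 0.359) and Kupffer cell genes (0.67, 0.00339, 0.530).

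The third comparison followed the lineage genes with another tracer, in which tdTomato marks cells that expressed Csf1r before cerulein. This and each later comparison was set as 1 library against 1 and was not tested. Resident macrophage genes were higher in tdTomato-positive cells for all 23 members, with a median log2 ratio of 0.64, at percentile 100 among 10000 random lists of matched expression. Plasma cells were 4.82% of tdTomato-positive and 0.363% of tdTomato-negative cells, and immunoglobulin transcripts in the macrophage sums stood at 1000 against 407 CPM (1.29). Cd163 stood at 256 CPM (exact Poisson interval 251 to 261, counting error only) against 81.5 CPM (78.5 to 84.5), Lyve1 at 227 (223 to 232) against 77.8 (74.9 to 80.7), and Timd4 at 85.6 against 44.6 CPM. Vsig4, a complement receptor gene, stood at 200 against 56.0 CPM (log2 ratio 1.82), and the B cell chemokine Cxcl13 at 438 against 84.9 CPM (2.35). The protease gene Ctsk had the highest ratio of those named by the rule (77.1 against 13.3 CPM, 2.45). MHC class II genes were lower for 8 of 10 members (median −0.24, percentile 0), with H2-Aa at 2843 against 4217 CPM (−0.57). Ccr2 stood at 255 against 338 CPM and the lipid-associated genes Gpnmb at 102 against 170 (−0.73), Fabp5 at −0.59 and Spp1 at 412 against 646 CPM (−0.65, and 0.05 over all cells that passed the quality filter). Most tdTomato-positive macrophages fell in clusters led by Cd209f and Cd163 (28.7%), Rsad2 and Ifit2 (22.6%) and Cd72 and H2-Ab1 (18.3%), and most tdTomato-negative in the latter pair (29.7% and 26%) and a cluster led by Gpnmb and Fcrls (24.7%).

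The collagen and matrix list had 8 genes higher and 23 lower in tdTomato-positive cells (median −0.13, percentile 0), with Col1a1 at 6.47 CPM (5.71 to 7.31) against 8.80 (7.85 to 9.83) and Dcn at 15.8 against 15.6 CPM. The fibrillar list stood at 0.01 (percentile 28.2). Acinar enzymes were higher for 18 of 18 genes (1.41, percentile 100, and −0.10 over all cells). Other lists at percentile 98.0 or above were alternative activation (0.31), inflammatory cytokines (0.23), Kupffer cell (0.45), alveolar macrophage (0.14), receptors of fibroblasts (0.13), dissociation stress (0.09) and phagocytosis receptors (0.08). At percentile 0.55 or below were cell cycle (−0.21), lipid-associated (−0.14), monocyte-derived (−0.10) and matrix protease genes (−0.07). Over all cells that passed the quality filter, inflammatory cytokines (−0.07), alveolar macrophage (−0.05), receptors of fibroblasts (−0.18), dissociation stress (−0.05), phagocytosis receptors (−0.10) and cell cycle genes (0.45) changed sign.

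The fourth comparison set pancreatitis against steady state within each lineage. Antigen-presentation genes were lower and cycling genes higher in both lineages. Summed mitochondrial transcripts stood at 72413 against 47448 CPM (log2 ratio 0.61) and ribosomal protein transcripts at 88312 against 154352 CPM (−0.81) in YFP-negative macrophages. In YFP-positive macrophages they stood at 0.00 and −0.31, so RNA quality or cell state moved with the YFP-negative comparison. Signs of other cells moved in each lineage, with hemoglobin at −1.23 in YFP-negative and 3.82 in YFP-positive and immunoglobulin at 0.58 and −1.23. H2-Aa stood at 974 CPM in pancreatitis and 5680 at steady state in YFP-negative macrophages (log2 ratio −2.54) and at 1290 against 7178 in YFP-positive (−2.48). All 10 MHC class II genes were lower (median −1.89 and −2.11, percentile 0 in both). All 20 cell cycle genes were higher (2.55 and 2.26, percentile 100), with Mki67 at 125 against 12.3 CPM in YFP-negative and 131 against 14.9 in YFP-positive macrophages. Interferon response genes were lower (−0.83 and −1.26), and alternative activation genes had medians of −0.40 (4 higher and 10 lower, percentile 3.16) and −1.55 (3 higher and 12 lower, percentile 0). Retnla stood at 103 against 2078 CPM in YFP-negative (−4.32) and 25.3 against 3598 in YFP-positive cells (−7.10), and Mgl2 at 26.4 against 881 CPM (−5.01) in YFP-negative cells. Lyve1 stood at 268 against 888 CPM in YFP-negative and 98.5 against 633 in YFP-positive cells, while Cd163 stood at 514 against 586 (−0.19) and 201 against 402 CPM (−0.997). The resident list as a whole had a median of −0.15 in YFP-negative (percentile 38.1) and −0.51 in YFP-positive cells (percentile 0).

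Matrix genes were higher in pancreatitis in YFP-negative macrophages and divided in YFP-positive, a difference between lineages that was not tested. The collagen and matrix list had 25 genes higher and 7 lower in YFP-negative macrophages (median 0.48, percentile 100, and 2.63 over all cells, which include fibroblasts), and 17 higher and 13 lower in YFP-positive macrophages (0.06, percentile 98.4, and −0.01 without called doublets). Col1a1 stood at 7.74 CPM (7.12 to 8.39) against 1.14 (0.906 to 1.42) in YFP-negative and 2.15 (1.73 to 2.64) against 0.664 (0.486 to 0.886) in YFP-positive macrophages. Other immune cells of pancreatitis held collagen transcripts too, as given above. Fibronectin, Fn1, stood at 801 against 106 CPM in YFP-negative (2.91) and 917 against 874 in YFP-positive macrophages (0.07). Spp1, an adhesive glycoprotein gene, stood at 411 against 26.9 (3.89) and 657 against 84.2 CPM (2.95). The collagenase activator Mmp14 stood at 25.8 against 4.06 CPM in YFP-negative cells, and matrix proteases and inhibitors had medians of 0.59 and 0.41. Monocyte-derived genes had a median of 0.75 in YFP-negative, with Ccr2 at 495 against 125 CPM, and −0.46 in YFP-positive cells (0.49 over all cells), with Ccr2 at 656 against 583 CPM. Acinar enzymes were lower (−2.74 and −2.97). The named genes with the highest ratios included Egr3, at 244 against 1.59 CPM in YFP-negative macrophages (6.56), and Clu (5.11). Clu was also a leading gene of the ductal or epithelial cluster. Those cells were 0.909% of YFP-negative cells in pancreatitis and 0.112% at steady state, so their RNA was not excluded as a source. Some genes, such as Rnasek, Rbm42 and Tnfsf13, were at least 4 times lower in both steady-state libraries than in every other macrophage library. Another software version had counted the steady-state libraries. Such genes were 7 of 10 named as higher in YFP-negative and 8 of 10 in YFP-positive cells. State and counting version could not be separated for these genes.

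The fifth comparison set PDAC against steady state and against pancreatitis. Resident genes were lower and hypoxia and inflammatory genes higher in both lineages. Of 23 resident genes 22 were lower than at steady state in each lineage (medians −2.41 and −2.38, percentile 0), with Lyve1 at 76.3 against 888 CPM in YFP-negative and 21.1 against 633 in YFP-positive macrophages, and Folr2 at 78.4 against 991 CPM in YFP-negative. All 19 glycolysis and hypoxia genes were higher (2.31 and 1.84, percentile 100). The glucose transporter gene Slc2a1 stood at 93.5 against 2.56 CPM in YFP-negative and 112 against 5.65 in YFP-positive cells, and Vegfa, the vessel growth factor that hypoxia induces, at 300 CPM (296 to 303) against 0.380 (0.251 to 0.554) and 417 (411 to 423) against 1.86 (1.56 to 2.21). Il1b stood at 2954 against 51.9 CPM in YFP-negative and 3983 against 115 in YFP-positive cells, and the inflammatory list at medians of 1.94 and 2.28. Arg1, which breaks down arginine, stood at 2306 against 7.02 CPM (8.17) and 2388 against 45.5 CPM (5.68). A PDAC cluster with Mmp12, Cxcl3 and Arg1 among its leading genes was held out of the class, since no macrophage marker was among its 10 leading genes. It held 462 YFP-positive and 1228 YFP-negative cells, 26% and 21% of the class with it added. Slc2a1, Vegfa, Egln3, Hilpda, Bnip3, Ndrg1 and Spp1 also led this cluster, so the PDAC values of hypoxia genes, Arg1 and Spp1 leave those cells out. Adding it moved 44 of 70 list medians and 44 of 80 named genes of the PDAC comparisons beyond counting error, and reversed 0.

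Monocyte-derived genes had medians of 3.16 in YFP-negative and 1.29 in YFP-positive cells of PDAC over steady state, with Chil3 at 192 against 1.72 CPM in YFP-negative cells. Of the 10 genes named as higher, 1 in YFP-negative and 3 in YFP-positive cells, such as Rnasek, were low in both steady-state libraries as above. Matrix remodelling genes were higher, with protease and inhibitor medians of 1.54 and 1.71. Mmp14 stood at 186 against 4.06 CPM in YFP-negative cells (5.21) and Mmp12, the macrophage elastase, at 557 against 2.93 CPM (7.15). Spp1 stood at 1787 against 26.9 and 1760 against 84.2 CPM, and Fn1 at 3040 against 106 and 2717 against 874 CPM. The collagen list as a whole had medians of 0.21 (percentile 95.3, and 1.78 over all cells) and 0.02 (percentile 77.7), Col1a1 being at 3.25 against 1.14 and 1.55 against 0.664 CPM. TGF-beta response genes (1.65 and 1.33), cell cycle genes (2.23 and 1.71) and growth factor ligands (0.74 and 0.63) were at percentile 100 in both lineages. Complement was lower in YFP-negative cells (−0.80, percentile 0.155), with C4b at 199 against 527 CPM, and MHC class II stood at −0.43 and −0.51. Against pancreatitis, MHC class II genes were higher in PDAC for 9 of 10 members in each lineage (medians 1.80 and 1.55), while summed mitochondrial transcripts stood at 46971 against 72413 CPM (−0.62) and ribosomal protein transcripts at 156249 against 88312 CPM (0.82) in YFP-negative, and at −0.24 and 0.25 in YFP-positive cells. Also against pancreatitis, all 19 glycolysis and hypoxia genes were higher (2.36 and 2.53) and resident genes were lower for 20 of 23 (−2.27 and −2.03). Arg1 (6.81 and 6.56) and Mmp12 (8.48 and 8.04) were again among the highest. Gas6, which helps macrophages clear dying cells, stood at 80.9 against 777 CPM (−3.25) and Igf1 at 31.6 against 345 CPM (−3.41) in YFP-negative cells. Acinar enzymes were lower than at steady state (−7.14 and −6.86), and immunoglobulin transcripts stood at 0.01 and −3.21. Against pancreatitis, summed acinar transcripts stood at −5.08 in YFP-negative and −4.95 in YFP-positive cells. Immunoglobulin stood there at −0.56 and −1.98 and hemoglobin at 0.07 and −4.83. Tumors were digested for longer than the steady-state and cerulein-treated pancreas, and the dissociation stress list stood at −0.03 and −0.04 over steady state (percentiles 26.4 and 34.7).

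**Figure D2:**
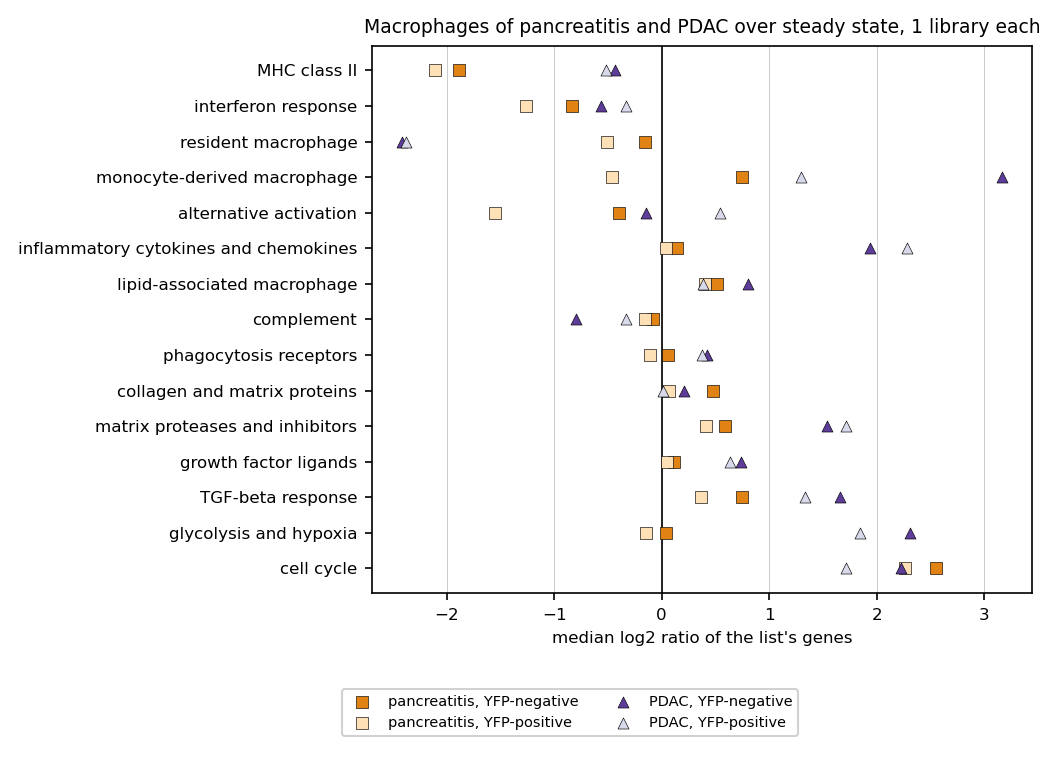
Median log2 ratio over steady state (x axis, no unit) of 15 gene lists (y axis) in YFP-negative (dark) and YFP-positive (pale) macrophages of pancreatitis (squares) and PDAC (triangles), 1 library each. MHC class II lies at −1.89 and −2.11 in pancreatitis and glycolysis and hypoxia at 2.31 and 1.84 in PDAC.

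The sixth comparison set YFP-negative against YFP-positive macrophages within liver and lung tumors. In the liver, tissue-resident Kupffer genes were higher in YFP-negative and monocyte genes in YFP-positive cells. Ribosomal protein transcripts stood at 90007 against 150524 CPM (log2 ratio −0.74) and immunoglobulin transcripts at 74.4 against 1136 CPM (−3.91) in the same comparison, and plasma cells were 0.0504% of YFP-negative and 3.32% of YFP-positive cells. Clec4f, a lectin of Kupffer cells, stood at 4176 against 1238 CPM (log2 ratio 1.75), Timd4 at 556 against 163 (1.77) and Cd163 at 742 against 209 CPM (1.83). All 14 Kupffer genes (median 1.74) and all 20 cell cycle genes (1.26, and −0.14 over all cells) were higher. Of 22 monocyte-derived genes 19 were lower (−2.82), with Ccr2 at 19.8 against 670 CPM (−5.01) and Ly6c2 at 3.60 against 212 CPM (−5.54). All 10 MHC class II genes were lower (−1.20), with H2-Aa at 3224 against 5772 CPM, and the inflammatory list stood at −1.21. The resident list had 16 genes higher and 7 lower (0.99). Most YFP-negative cells fell in clusters led by Apoc1 and Chp2 (36.1%), Fosb and Cxcl1 (19.1%) and Hebp1 and Dmpk (14.7%), and YFP-positive cells in clusters led by Ccl8 and Cxcl9 (29.6%), Spp1 and Gpnmb (24.8%) and the first (12.2%). In Kupffer cells alone the differences were smaller, with the Kupffer list at 0.07, monocyte-derived genes at −1.08, MHC class II at −0.30 and the resident list at 0.11. TMM scaling would shift every liver gene by −0.14 and every YFP-positive gene of pancreatitis over steady state by 0.12 on the log2 scale, and less than 0.1 elsewhere.

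In the lung, alveolar macrophage genes were higher in YFP-negative cells for 18 of 19 (median 0.35), with Siglecf at 132 against 85.9 CPM (0.61) and Ear1 at 380 against 279 CPM (0.45). Scgb1a1, a secretory product of airway epithelium, stood at 74.1 against 1.93 CPM (4.68), in suspensions where lung epithelial cells were 4.81% of YFP-negative (801 of 16645) and 0.569% of YFP-positive cells (82 of 14406). Immunoglobulin transcripts stood at −1.39. All 10 MHC class II genes were lower (−1.53), with H2-Aa at 215 against 1462 CPM (−2.76). Complement genes C1qa (39.8 against 601 CPM, −3.88) and C1qb (−3.94) and the lipid carrier Apoe (202 against 2242 CPM, −3.47) were lower, as were 20 of 21 inflammatory genes (−0.99), such as Ccl5 at 4.67 against 27.2 CPM. Unlike the pancreas and liver pairs, resident genes were lower for 17 of 23 (−0.43), with Pf4 at 10.6 against 49.8 CPM. The YFP-negative cells lay in clusters led by Ereg and Tnf (21.4%), Marco and Ear6 (20.8%), Gal and Cidec (19.7%) and Nav2 and Cidec (18.2%), and the YFP-positive cells in a cluster led by Syngr1 and Spp1 (19%) and the first of these (14.4%). Within alveolar macrophages alone, MHC class II (−0.59), inflammatory genes (−0.30) and resident genes (−0.17) were lower in YFP-negative cells.

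The seventh comparison asked how pancreas fibroblasts differ in pancreatitis and after macrophage depletion. In pancreatitis, fibroblasts held more transcripts of fibrillar collagen and contractile genes than at steady state. Ribosomal protein transcripts stood at 131304 against 179879 CPM (log2 ratio −0.45) and immunoglobulin transcripts at 120 against 20.1 CPM (2.52). Col1a1 stood at 6530 CPM (6516 to 6543) against 1235 (1229 to 1241) (log2 ratio 2.40), Col3a1 at 22145 against 5737 (1.95) and the matricellular gene Postn at 1868 against 199 CPM (3.22). The crosslinking enzyme Lox stood at 368 against 74.5 CPM (2.29), and Acta2, the actin of myofibroblasts, at 31.0 against 1.30 CPM (3.80). Of 27 fibrillar collagen genes 23 were higher (median 0.60, percentile 100), and 23 of 32 collagens and matrix proteins (0.67, percentile 100). All 19 interferon response genes were higher (1.29), with Isg15 at 59.9 against 21.1 CPM. TGF-beta response (0.93), matrix proteases (0.60), myofibroblast genes (0.55) and growth factor ligands (0.46) were higher too. Dcn stood at 10970 against 14545 CPM (−0.41), and 14 of 15 universal fibroblast genes were lower (−0.58, percentile 1.42), with Pi16 at 406 against 1378 CPM. Saa3, an acute-phase gene, had the highest ratio (328 against 0.306 CPM, 7.98), followed by Thbs4 (301 against 2.79 CPM, 6.32). Acinar enzymes were lower (−4.62). Most steady-state fibroblasts fell in clusters led by Efhd1 and Pi16 (36.9%), Cxcl14 and G0s2 (29.6%) and Ces1d and Gsn (24.8%), and most IgG fibroblasts in clusters led by Col6a5 and Has1 (34.2%), Dmkn and Prg4 (25.8%) and Thbs4 and Tnc (17.8%).

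After macrophage depletion, collagen transcripts were lower than with IgG and antigen-presentation transcripts higher. Col3a1 stood at 13516 CPM (13498 to 13534) against 22145 (22121 to 22170) (log2 ratio −0.71), Col1a1 at 5550 (5539 to 5562) against 6530 (−0.23), Postn at 1410 against 1868 (−0.41) and Tnc at 25.9 against 50.1 CPM (−0.92). Of 32 collagens and matrix proteins 27 were lower (median −0.30, percentile 0), as were 19 of 27 fibrillar collagen genes (−0.16, percentile 0). Lox was at 443 against 368 CPM (0.27) and Acta2 at 29.2 against 31.0 CPM (−0.08). MHC class II genes were higher for 8 of 9 (1.45, percentile 100), Cd74 being at 25.8 CPM (25.0 to 26.6) against 2.60 (2.34 to 2.88) and H2-Aa at 17.4 (16.7 to 18.1) against 2.04 (1.82 to 2.29). Mesothelial cells, whose cluster had Cd74 and H2-Ab1 among its leading genes, were 0.785% (113 cells) of the IgG and 1.88% (242 cells) of the depleted library, so their RNA was not excluded as a source. Interferon response genes were higher for 18 of 19 (0.70), with Stat1 at 141 against 57.0 CPM and Cxcl10 at 39.9 against 9.39 CPM, and the class I gene H2-K1 stood at 1423 against 468 CPM (1.60). Ctla2a, whose exons overlap Gm49391, had the highest ratio (2.45), and Thbs4 the lowest (84.5 against 301 CPM, −1.82). Cell cycle genes were lower (−0.39, percentile 0, and 0.10 over all cells), with Mki67 at 2.22 against 6.87 CPM. Universal fibroblast genes were higher (0.25, percentile 99.9), Pi16 being at 905 against 406 CPM. Acinar enzymes were higher for 19 of 19 genes (1.34), and hemoglobin stood at 64.0 against 0.716 CPM (5.24). Most depleted fibroblasts fell in clusters led by Ctla2a and Mmp11 (28.6%), Iigp1 and Cxcl10 (27.8%) and Thbs4 and Tnc (16.8%). Depletion here means anti-CSF1 together with clodronate liposomes, and the share of macrophages left in the pancreas was not measured.

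**Figure D3:**
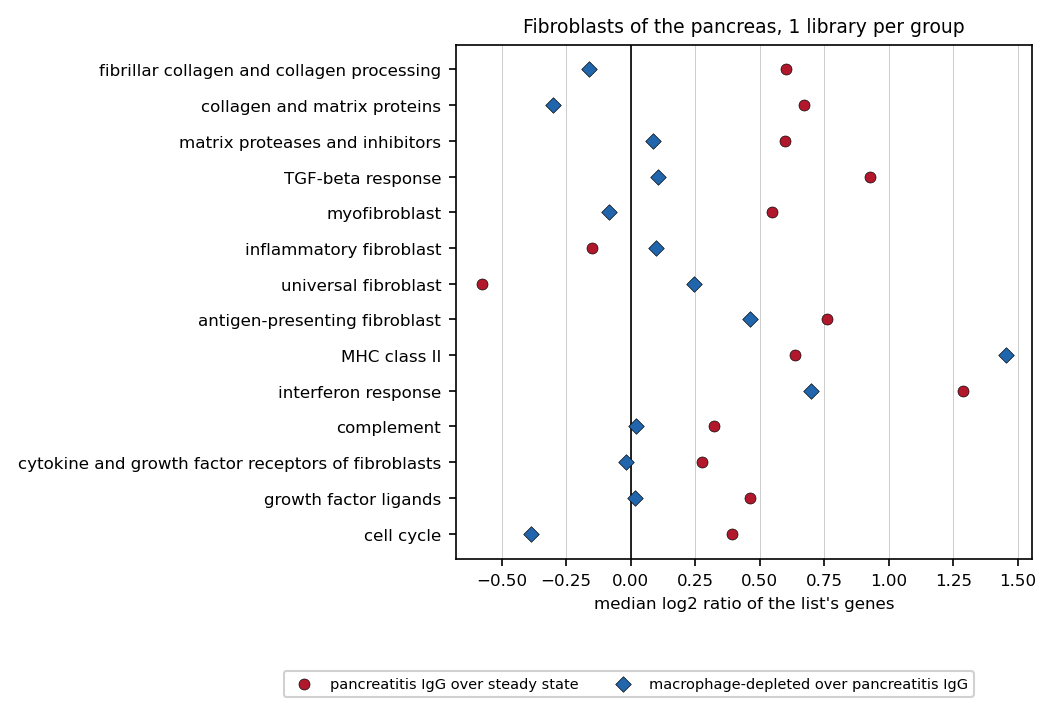
Median log2 ratio (x axis, no unit) of 14 gene lists (y axis) in fibroblasts of pancreatitis with IgG over steady state (circles) and of macrophage-depleted over IgG pancreatitis (diamonds), 1 library per group. Collagens and matrix proteins lie at 0.67 and −0.30 and MHC class II at 0.64 and 1.45.

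Positions follow GENCODE vM21 on GRCm38 (mm10), counted from 1. Lyve1 (ENSMUSG00000030787) lies on chromosome 7 from 110850607 to 110863239, Cd163 (ENSMUSG00000008845) on chromosome 6 from 124304656 to 124330527 and Ccr2 (ENSMUSG00000049103) on chromosome 9 from 124101950 to 124113557. H2-Aa (ENSMUSG00000036594) lies on chromosome 17 from 34282744 to 34287823 and Col1a1 (ENSMUSG00000001506) on chromosome 11 from 94936224 to 94953042. Col3a1 (ENSMUSG00000026043) lies on chromosome 1 from 45311538 to 45349706 and overlaps Gm47302 on its strand.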

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

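Tests of whether free RNA made up the whole level in macrophages were chosen after the result was seen, and so were the size limit of 0.3 and the percentile limits that chose the list differences below. Each difference between tissues or lineages below rests on 1 pair of libraries and was not tested.

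The YFP-negative over YFP-positive ratio of some lists went one way in a tissue and the other way in another. Resident macrophage genes had medians of 0.52 at steady state, 0.72 in pancreatitis, 0.62 in PDAC and 0.99 in liver tumor, and −0.43 in lung tumor, but 0.10 in Kupffer cells alone and −0.08 in alveolar macrophages alone. Those 2 values narrow the makeup to a single named class, but the mix of clusters within it was not matched between lineages. Alveolar macrophage genes stood at −1.06 at steady state and 0.35 in the lung, and cell cycle genes at −0.32 at steady state and 1.26 in the liver, which became −0.14 over all cells that passed the quality filter. Alternative activation stood at 0.47 in pancreatitis, −1.48 in the liver and −0.43 in the lung. Genes of universal fibroblasts stood at 0.30 in pancreatitis and −0.68 in the liver, and those of antigen-presenting fibroblasts at 0.63 in pancreatitis and 0.33 in PDAC, against −0.98 in the liver and −0.30 in the lung (0.044 over all cells). Between lineages, pancreatitis over steady state gave monocyte-derived genes 0.75 in YFP-negative and −0.46 in YFP-positive macrophages, and antigen-presenting fibroblast genes 1.49 and −0.65. Neither opposition held under every alternative, since the YFP-positive values became 0.49 over all cells and 0.15 with each cell weighted the same. A cluster led by myelin genes such as Plp1, Mog and Mbp held 3.03% of YFP-positive and 1.83% of YFP-negative steady-state cells, with median counts of 1076 and 1068 UMIs, and was used in no comparison. No explanation of that cluster was tested.

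The collagen and matrix list had a higher median in YFP-negative macrophages of the pancreas. The 16 collagen genes summed were higher in other immune cells of the YFP-negative libraries too, with a median log2 ratio of 1.21 over the 3 pairs (0.22, 0.30 and 0.00 in macrophages), so free RNA in the suspension may bring part of the difference, though the steady-state value rests on 11 counts on the YFP-negative side. Without called doublets the median log2 fold change of the collagen and matrix list was 0.951, which argues against called doublets as the source. Whether the caller finds doublets of macrophages and fibroblasts was not tested, so doublets that it missed stay open. Col1a1, Col1a2 and Col3a1 together lay above their level in other immune cells by more than counting error in 3 of the 6 libraries, which argues against free RNA as the whole level only weakly, since it sits exactly on a bound of 3 that was written after the values were seen. Expression of collagen by the macrophages themselves stays open and was not tested.

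Acinar enzymes such as Clps and Prss2 were higher in YFP-negative macrophages of the pancreas. Their sum was also higher in other immune cells of the YFP-negative libraries, with a median log2 ratio of 0.649 over the 3 pairs, although the steady-state pair went the other way (−1.14 over 31 other immune cells on the YFP-negative side), and free RNA in the suspension may bring part of the difference. The level in macrophages lay above that in other immune cells by more than counting error in 5 of the 6 libraries. In pancreatitis it stood at 1160 against 939 CPM in the YFP-negative and 703 against 598 CPM in the YFP-positive library. The steady-state YFP-positive library went the other way, at 3702 against 4518 CPM. This argues only weakly against free RNA as the whole level, since counting error does not cover differences in free RNA between cell classes. Without called doublets the median log2 fold change of the list was 0.679, which argues against called doublets as the source. Summed acinar transcripts in YFP-negative macrophages of pancreatitis stood at 1160 CPM with and without called doublets. Whether the caller finds doublets of macrophages and acinar cells was not tested, so doublets that it missed stay open. Uptake of acinar material by macrophages stays open and was not tested.

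The steady-state macrophage libraries held at most 1.39 CPM of Rnasek, 0.265 of Rbm42, 17.2 of Nme2 and 79.1 of Atp5l over all cells. They belong to 72 genes that stood at least 4 times higher in every other macrophage library. Of these 37.5% had an exon overlapping another gene on the same strand, against 8.93% of 8510 other genes (Fisher's exact test, two-sided p = 5.36e-11), which is consistent with the other counting version named in the headers of the steady-state libraries. Their median log2 ratio of pancreatitis over steady state in fibroblasts, counted with a single version, was −0.119 (quartiles −0.432 and 0.238). This argues against a difference between steady-state and diseased pancreas that fibroblasts share. The median of 2.75 in macrophages sets the lowest of the 10 other libraries over the highest steady-state one. That ratio chose the 72 genes, so it is no contrast to the fibroblasts. A difference limited to macrophages stays open for the others, most of the 72, which overlap no other gene, such as Arhgap30 and Rasgef1b.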

How the results depend on the processing

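The PDAC cluster with Arg1 added, the doublet and stricter filters for gene lists, list medians without genes low in the steady-state libraries, and Kupffer or alveolar cells alone were tests chosen after the results were seen. The 5 counts of genes and lists gave 64 values under alternatives, of which 54 equalled the main count or lay within 1.5-fold of it. Beyond that range 9 went up and 1 went down. Lineage genes by edgeR, 0 in each direction, stayed at 0 with DESeq2 size factors, all cells, no cycling clusters, no called doublets, the stricter filter, the PDAC cluster added, acinar, stress and other marker genes left out, and no state block (no pairing of libraries), for both the 3-pair and 5-pair fits where run. By DESeq2 there were 150 genes higher and 42 lower over 3 pairs, and 106 and 99 over 5 pairs. In simulated data DESeq2 made more false calls than its threshold allows, over 3 pairs and over 5 pairs. Genes higher in YFP-negative macrophages numbered 5 with no filter on low counts and 1 with the tdTomato pair added, Chp2 (log2 fold change 1.01, SE 0.0732, edgeR adjusted p = 0.0484). Leaving out each pair gave 0 to 43 genes higher and 0 lower over 3 pairs, and 0 over 5 pairs. The count of 14 lists fell to 0 with an estimated correlation and ranged from 15 to 22 over the pairs left out, and was 18 over all cells, where all 14 were among them in the same direction. Simulated 2-fold changes were called at this number of libraries, with each gene's spread drawn toward that of other genes. The real Pla2g2d did not pass at a log2 fold change of 1.10 (edgeR adjusted p = 0.232). The simulation therefore does not show that real 2-fold changes would be called. The cause of the differences between settings was not tested.

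Of 993 alternative values of 177 list medians, each a list in a given comparison, 523 stayed within counting error and 440 moved. The other 30 values, from 27 of these medians, reversed, 22 of them over all cells that passed the quality filter. Of 1220 values of 220 named genes, 711 stayed, 508 moved and 1 reversed. Over all cells the tdTomato resident median was 0.39 (0.64 in macrophages, and 0.71 with each cell weighted the same), and reversals were inflammatory cytokines −0.065, phagocytosis −0.10, cell cycle 0.45, stress −0.051, acinar −0.10, inflammatory fibroblast −0.30, antigen-presenting fibroblast −0.10, alveolar −0.047, receptors of fibroblasts −0.18 and the gene Spp1 at 0.046. Over all cells, YFP-negative pancreatitis over steady state gave collagens 2.63 (0.48 in macrophages) and receptors of fibroblasts 0.29, YFP-positive gave monocyte-derived genes 0.49, and YFP-negative PDAC over steady state gave collagens 1.78 (0.21 in macrophages). All cells include fibroblasts, by construction. PDAC over pancreatitis gave inflammatory fibroblast −0.010 in YFP-negative and universal fibroblast −0.013 in YFP-positive cells. In the liver all cells gave resident 1.55, cell cycle −0.14 and alveolar 0.0082, and in the lung growth factors 0.10, lipid-associated 0.15, cell cycle 0.057, glycolysis 0.00050, universal fibroblast 0.37 and antigen-presenting fibroblast 0.044. Depleted over IgG fibroblasts gave cell cycle 0.10. Weighting each cell the same gave collagens 0.67 in YFP-negative pancreatitis and 0.42 in YFP-negative PDAC over steady state, antigen-presenting fibroblast 0.15 in YFP-positive pancreatitis, liver resident 0.80 and fibrillar collagen 0.47 in IgG over steady-state fibroblasts. Under TMM these last medians were 0.85 and 0.51 (0.99 and 0.60 by totals). Without called doublets, YFP-positive pancreatitis over steady state gave collagens −0.012 and fibrillar collagen −0.010, and the liver resident list 0.90. Kupffer cells alone gave resident 0.10, complement −0.0081, myofibroblast 0.00030 and alveolar 0.041, and alveolar macrophages alone gave resident −0.082, glycolysis 0.011 and universal fibroblast 0.071. These use the genes measured in the whole class, so they differ from the medians over each class's own measured genes. The stricter filter reversed none. The cause of these reversals was not tested.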

Other observations

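The splits of libraries and their statistics were planned, and the correlations below were chosen after the data were seen. Of the 10 ways to split the 6 pancreas libraries 3 against 3, edgeR called 0 genes for the real lineage split and up to 173 for another. With a real count of 0, it was fixed in advance that all 10 would give as many, so this count decides nothing. The 10 splits were also too few for a share under 0.05. For lists past camera, 4 of the 10 splits gave as many as the real 14, and the highest other split gave 17. The splits with 173 genes parted 1 pair, so with state as a block they measured the lineage difference within that pair. That pair was the steady-state one, so these splits point to a difference between its libraries and not to one between states. No split that parted every pair called a gene. Among the 3 other splits that parted every pair, 275 to 342 genes had an unadjusted edgeR p under 0.05, against 1168 for the real split, and 9 to 17 lists passed.

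Over 5 pairs, 100 of the 126 possible splits were drawn. The real split called 0 genes, so that all 100 would give at least as many was again fixed in advance and decides nothing. The highest other count, 816, came from splits that parted 1 pair and so measured the lineage difference within it. For lists, 44 of the 100 gave at least the 13 of the real split, though these included splits that parted fewer pairs. The 13 other splits that parted every pair gave 150 to 791 genes at an unadjusted edgeR p under 0.05, against 1558 for the real split, and 5 to 19 lists, so chance cannot be excluded for the number of lists.

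Lineage ratios of single genes were compared between pairs across genes, which are not independent replicates, for 15 combinations of pairs. YFP-negative over YFP-positive ratios in pancreatitis correlated with tdTomato-positive over tdTomato-negative ratios at Pearson 0.546 and Spearman 0.471 over 5334 genes. Between states of the YFP pancreas libraries the values were 0.124 and 0.0574 between steady state and pancreatitis, 0.151 and 0.245 between steady state and PDAC, and 0.150 and 0.107 between pancreatitis and PDAC. Pancreatitis and liver tumor stood at 0.416 and 0.539, liver and lung tumor at 0.360 and 0.462, and pancreatitis and lung tumor at 0.343 and 0.563. The Spearman values of pancreatitis with liver and with lung tumor lay above its value with tdTomato, 0.471. Against the tdTomato ratios, steady state stood at −0.0555 and 0.196, PDAC at 0.376 and 0.274, liver tumor at 0.165 and 0.296 and lung tumor at 0.0981 and 0.306. Steady state stood at 0.396 and 0.170 with liver tumor and 0.0507 and −0.137 with lung tumor, and PDAC at 0.131 and 0.131 with liver tumor and 0.0665 and 0.0429 with lung tumor.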
